A study of Mus musculus with 5 samples.

How the data were processed

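Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into accessible DNA, in mouse pro-B cells. Fetal liver cells without Ebf1 had been given wild-type EBF1 (wt) or one of the forms called dC and YmA by transduction. After 8 days in culture, 50000 cells positive for the B-lineage surface protein CD19 were sorted per library. 5 libraries were used: wt replicate 2, dC replicates 1 and 2, and YmA replicates 1 and 2. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate fetuses or transductions, so the spread between them may be technical.

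The deposited files are peak lists, 1 per library, so peaks were called by the authors on each library separately. Bowtie2, SAMtools, MACS2 and deepTools are named in the submitters' processing notes, without versions, and the build is GRCm38 (mm10). The deposited peak names carry a tag for a filtered file of short fragments, so peaks appear to have been called on short fragments after filtering. The filters themselves, the treatment of the transposase offset, of duplicates and of mitochondrial reads are not given in the sources used here. The deposited fold of each peak is the authors' ratio of its summit over the local background. The deposited −log10 p and −log10 q values are the authors' significance for the peak against that background. The smallest deposited −log10 q was 3.00, which is a q-value threshold of 0.001. The deposited score is 10 times −log10 q, cut to a whole number, in all peaks but 4, where it is lower by 1. A fold, a −log10 value or a score belongs to its own list and was used to describe, rank or filter peaks within that list. The odds ratio of co-absence of a pair of libraries is the exception. It was taken over regions held by all the other libraries, within deciles of their lowest −log10 p. This compares −log10 p values between lists whose depths may differ.

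The lists hold no read counts, so the sequencing depth of each library is unknown. A region without a peak is a region where no peak passed the authors' threshold, and a shallower or noisier library has more of them. Confidence intervals are 95% Wilson intervals, except for the odds ratios of co-absence described below. For those, they are 95% percentile intervals over bootstrap resamples, in which regions were redrawn with replacement. All intervals cover counting error over regions of the lists compared and not the variation between cultures.

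Peaks on the 19 autosomes and X were merged into 1 union of regions wherever peaks of any lists overlapped by at least 1 bp. A region was present in a library if it held at least 1 of that library's peaks, and absent otherwise. Every comparison used the same union. With 1 wt library, no test between wt and a mutant was made and no p-value is given. Counts of wt regions absent from both libraries of a mutant were set beside the regions private to each mutant library. For dC against YmA, the 3 splits of the 4 libraries into pairs were compared, for which the smallest two-sided exact p is 0.333. The overlap of the 2 lists of absent wt regions was set beside that of independent lists and beside 1000 simulations that drew absence at random within 20 bins of wt fold.

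A RefSeq gene table of assembly GRCm38.p6, the same build, gave gene positions without strand, exons or sequence. Regions were therefore classed as lying within 1 kb of either end of a gene, inside a gene, or between genes. Only protein-coding genes and the gene segments of antigen receptor loci were used. Genes of other kinds were ignored, so a region called between genes may lie in one, and distances are to the nearest gene used. Promoters, exons and introns were not told apart, and the planned search for EBF motifs was not made. 11 gene lists with 166 members, all found in the gene table, were fixed before the data were examined, as were the alternatives except where stated. A locus was the gene body plus 10 kb on each side. The share of a list's wt regions absent from a mutant was ranked among 10000 random gene lists of the same size, matched on the number of wt regions per locus. Wt fold and closeness to a gene end were not matched. The median wt fold ran from 8.43 for natural killer and innate lymphoid genes to 12.5 for housekeeping genes. A percentile can therefore partly reflect peak strength. For the ranking, a region at several loci of a list was counted at each of them. The printed shares count it once, so they can differ slightly from the ranked ones. That percentile describes these libraries and is not a p-value.

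The genes named were Ebf1 and, for wt against each mutant, up to 20 genes of the 4 B-cell lists with a wt region absent from both mutant libraries, ranked by wt fold. The 10 absent regions of highest wt fold were added. For the other directions, the 10 regions whose worse rank within the 2 lists was best were taken, and from each of the other lists up to 3 genes with the most absent or additional regions. Results outside these rules are said to have been chosen after their values were seen.

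Alternatives were a −log10 q of at least 5, lists cut to the strongest 13905 peaks by −log10 p (the length of the shortest list), sharing defined by an overlap of 50% of the shorter peak or by summits within 250 bp, all contigs, leaving out each mutant replicate in turn, and replicate number 2 only. Loci were also taken with 50 kb on each side. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. It was tested on simulated data in which 2000 of 26242 regions were removed from both dC lists. 100% of them were recovered with 0 false calls, and the Jaccard index was checked against bedtools 2.31.1. The simulated lists were slightly shifted copies of well-separated wt peaks, without differences in depth or noise. The recovery therefore checks the code and gives no error rate for absence in the real lists. With absence from dC drawn at random over 42697 regions and raised at 1 gene list, that list ranked at percentile 100 of random lists and the 10 others between percentiles 8.43 and 69.8. Peaks on the mitochondrial genome, chromosome Y and unplaced contigs were left out of the main comparisons.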

Results

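ATAC-seq peak lists from pro-B cells carrying wild-type EBF1, dC or YmA were compared. EBF1 is a transcription factor needed for commitment to the B lineage, and the series asks about phase separation in its ability to open closed chromatin. In earlier work on EBF1, dC has denoted removal of the C-terminal domain. The labels do not describe YmA further. There was 1 wt library, replicate 2, and 2 libraries each of dC and YmA. The cells had been sorted for CD19, so all libraries come from cells that had turned on this B-lineage marker.

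The wt list held 29305 peaks. The dC lists held 13927 peaks in replicate 1 and 26100 in replicate 2, a mean of 20013.5 ± 8608 (SD, n = 2). The YmA lists held 31827 and 25317 peaks, a mean of 28572 ± 4603 (SD, n = 2). The difference between the 2 mutants lay within the spread of the dC replicates. Peaks covered 5203 kb in wt, 2277 and 4686 kb in dC and 5883 and 4748 kb in YmA. The median fold enrichment was 9.27 in wt, 8.12 and 9.51 in dC, and 9.89 and 9.91 in YmA. dC replicate 1 had the fewest peaks and the lowest median fold of the 5 libraries. Read depth is unknown, so the shorter list cannot be assigned to the library or to the cells.

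The lists merged into 42697 regions, of which 29130 were in wt and 11432 in all 5 libraries. Replicates shared little more than libraries of different mutants did. The Jaccard index of covered bases was 0.417 for the dC pair and 0.603 for the YmA pair, a mean of 0.510. Over the 4 dC and YmA combinations it averaged 0.480 ± 0.119 (SD), and the difference of 0.0304 was below that spread. The spread lay mostly between dC replicate 1 (0.354 and 0.404) and dC replicate 2 (0.578 and 0.583). The YmA pair had the highest index of the 10 pairs, also in lists of equal length (0.662). dC replicate 1 shared most with dC replicate 2, but dC replicate 2 shared more with either YmA library. wt shared 0.368 and 0.536 with the dC libraries and 0.567 and 0.555 with the YmA libraries. Of the peak regions of dC replicate 1, 92.0% were in dC replicate 2 and 94.7% were in YmA replicate 1, so this list was mostly a subset of the longer ones.

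The first comparison asked which regions open with wild-type EBF1 lacked a peak with dC. Of the 29130 wt regions, 8612 (29.6%, 95% CI 29.0 to 30.1) were absent from both dC libraries. The missing regions were mostly weak ones, with a median wt fold of 6.81 against 9.30 for all wt regions. Among the 12875 wt regions of at least 10-fold enrichment, 1050 (8.16%, CI 7.69 to 8.64) were absent from both. The regions of highest wt fold among them lay 45.2 kb from Lifr, the receptor of leukaemia inhibitory factor (chromosome 15, 7045157 to 7045407, 30.0-fold in wt), and at an end of Sacs (chromosome 14, 61137535 to 61137745, 27.3-fold). Both also had a peak in each YmA library. So did regions near Actl7b (27.3-fold in wt), Efemp1 (24.1-fold), Zfp704 (24.0-fold) and Ctnnbl1 (23.8-fold), and regions inside Prodh2 (23.3-fold), Gopc (23.1-fold) and Trappc9 (23.0-fold). A region 1.34 kb from Crygd (23.9-fold in wt) had a peak in YmA replicate 2 alone among the mutant libraries. The count depended on dC replicate 2: in dC replicate 1 alone 16652 wt regions were absent. With all lists at equal length 2562 wt regions (18.5%) were absent from both dC libraries, beside 2568 regions private to dC replicate 1 and 1897 private to dC replicate 2 among the same 3 lists. In the full lists the private counts were 565 and 5200. Each dC library had a sister library in this comparison and wt had none, so the private counts cannot show a loss particular to wt.

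**Figure D1:**
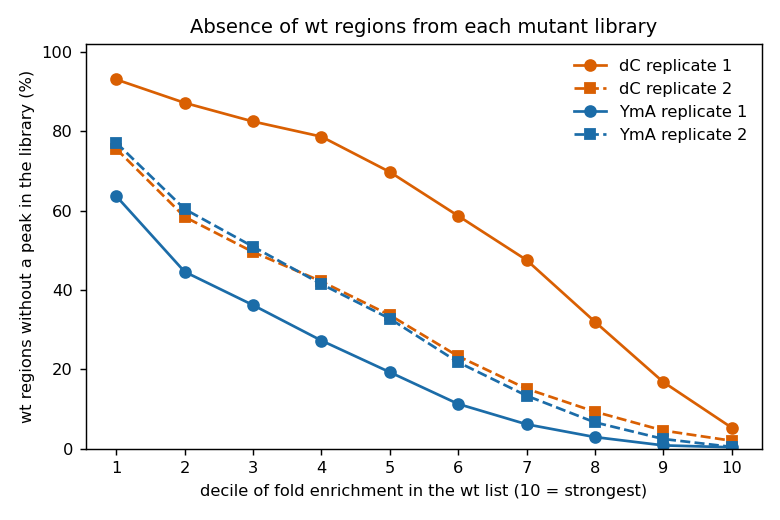
Percent of wt regions without a peak in each mutant library (vertical axis), by decile of fold enrichment in the wt list (horizontal axis, 10 being the strongest); colours mark dC and YmA, and circles with solid lines and squares with dashed lines mark replicates 1 and 2. In the strongest decile 5.32% and 2.03% of wt regions had no peak in dC replicates 1 and 2, and 0.378% and 0.481% in YmA replicates 1 and 2.

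Most wt regions at B programme genes had a peak in at least 1 dC library. Of 89 wt regions at the 30 B programme loci, 18 (20.2%, CI 13.2 to 29.7) were absent from both dC libraries, at percentile 8.86 of matched random gene lists, and at percentile 46.0 in lists of equal length. None of the wt regions at Cd19, Cd79a, Igll1 or Vpreb1 was absent from both. These genes lie outside the naming rules and were chosen after their values were seen, from several such genes of the list. The loci of Igll1 and Vpreb1 overlap, so the same regions can count for both. Igll1 and Vpreb1 encode the surrogate light chain of the pre-B cell receptor. Cd79b, a signalling chain of that receptor, had 2 of its 4 wt regions absent, the stronger at chromosome 11, 106314507 to 106314678 (11.5-fold in wt). Rag2, a subunit of the V(D)J recombinase, lacked 1 of its 2 wt regions (9.50-fold), Blnk, an adaptor in pre-B cell receptor signalling, 1 of 5 (9.38-fold), Cd22 1 of 3 (8.48-fold), Ralgps2 2 of 3 (8.83-fold) and Cnr2 2 of 4 (9.27-fold for the strongest). The sort for CD19 selected for cells in which at least part of this programme was active. Without dC replicate 2 the share was 51.7%.

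Among B-lineage transcription factors, 21 of 107 wt regions (19.6%, CI 13.2 to 28.1) were absent from both dC libraries, at percentile 1.83 of random lists, but at 38.5 in lists of equal length. The strongest lay inside Bach2, a transcriptional repressor of the B lineage, at chromosome 4, 32579987 to 32580317. It had a fold of 17.4 in wt, 13.4 in YmA replicate 1 and 14.7 in YmA replicate 2. Bach2 lacked 3 of 13 wt regions, Tcf3, which encodes E2A, 2 of 6 (9.93-fold for the strongest), Etv6 3 of 5 (8.17-fold), Pou2f2 2 of 6 (8.62-fold) and Irf4 1 of 3 (8.45-fold). Of the genes for pre-B cell receptor signalling, 24 of 80 wt regions (30.0%, CI 21.1 to 40.8) were absent, at percentile 62.8, or 17.1% in lists of equal length. Without dC replicate 2 the transcription factor share was 57.9%, the signalling share 58.8% and that of later B-cell genes 44.0%. The signalling regions absent from both dC libraries included those at Pik3ap1 (10.8-fold), Prkcb (9.47-fold), Bank1 (9.28-fold), Plcg2 (7.95-fold), Pik3cd (7.91-fold), Dapp1 (7.77-fold) and Btk (7.71-fold). At later B-cell genes 7 of 25 were absent (28.0%, CI 14.3 to 47.6, percentile 67.0), including both wt regions of Ms4a1, which encodes CD20, and 1 of 3 at Cxcr5.

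The second comparison asked the same of YmA. Of the wt regions, 5144 (17.7%, CI 17.2 to 18.1) were absent from both YmA libraries, with a median wt fold of 6.31. Among those of at least 10-fold enrichment in wt, 297 (2.31%, CI 2.06 to 2.58) were absent, against 1050 for dC. The highest wt fold of an absent region was 18.8, inside Clip2 (chromosome 5, 134518403 to 134518652). It was followed by regions inside Eef2k (18.5-fold), Srprb (18.4-fold) and Sdk2 (18.3-fold) and a region 425 kb from Ctnna2 (18.3-fold). The next lay 42.5 kb from Igkv1-117 (17.6-fold) in the immunoglobulin kappa locus, inside Dtx1 (17.2-fold), 17.6 kb from Steap3 (16.8-fold), and inside Scrt2 (16.3-fold) and 4932438H23Rik (16.2-fold). None of these 10 had a peak in a dC library either. In YmA replicate 2 alone 8968 wt regions were absent. With lists of equal length 2163 (15.6%) were absent from both, beside 1360 and 1653 regions private to YmA replicates 1 and 2. In the full lists the private counts were 5864 and 2091. Here too wt had no sister library and each YmA library had one, so the private counts cannot show a loss particular to wt.

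At B programme loci 9 of 89 wt regions (10.1%, CI 5.41 to 18.1) were absent from both YmA libraries, at percentile 7.52 of random lists. At transcription factor loci it was 10 of 107 (9.35%, CI 5.16 to 16.4, percentile 2.52), at signalling loci 9 of 80 (11.3%, CI 6.03 to 20.02, percentile 10.6) and at later B-cell loci 2 of 25 (8.00%, CI 2.22 to 25.0, percentile 20.4). In lists of equal length the first 2 lay at percentiles 18.8 and 18.3, and the last 2 at 54.0 and 61.4. No absent region at these loci reached 10-fold in wt. The strongest were at Cnr2 (9.27-fold), Ms4a1 (9.13-fold), Erg (8.43-fold), Bach2 (8.11-fold), Pik3cd (7.91-fold), Dapp1 (7.77-fold), Btk (7.71-fold), Lyn (7.22-fold), Myb (7.19-fold) and Fcrla (6.99-fold). Inpp5d, Ets1, Card11, Rasgrp3, Fcer2a, Bst1, Elf1, Irf8, Vpreb3 and Pou2af1 each held a weaker one, between 6.89-fold and 5.57-fold. Without YmA replicate 1 the shares were 21.3% for the B programme, 20.6% for transcription factors, 22.5% for signalling and 24.0% for later B-cell genes.

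The regions missing with the 2 mutants overlapped. 4357 wt regions (15.0%, CI 14.6 to 15.4) were absent from all 4 mutant libraries, which is 84.7% of those absent from YmA and 50.6% of those absent from dC. Independent lists would share 1521, and simulations that kept the dependence on wt fold shared 2720.5 on average and at most 2793. Both lists are defined by the same wt library, so part of the excess may come from that library. The number of regions private to wt was similar to the 4242 private to YmA replicate 1, and above the 296, 2263 and 1594 private to dC replicates 1 and 2 and YmA replicate 2. In lists of equal length wt had 1492 private regions, dC replicates 1 and 2 had 1875 and 998, and YmA replicates 1 and 2 had 636 and 880. Each mutant library had a sister library and wt had none, so these counts are not like for like. 4255 regions absent from both dC libraries were present in at least 1 YmA library.

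In the other direction, 761 regions were in both dC libraries and not in wt, and 2926 were in both YmA libraries and not in wt. At equal list length these were 1552 and 1594, so the mutants no longer differed by much. The highest ranked of the first set lay inside Lck, a T-lineage kinase (chromosome 4, 129558293 to 129558531, 11.8-fold and 15.4-fold in the dC lists). Others lay inside Slc14a2, C4bp and Mgst2, at an end of Dennd3, near Lrrk1, Rad23b, Umodl1 and Dmxl1, and 242 kb from Gm38821. These 10 regions also had a peak in both YmA libraries. For YmA the 2 highest ranked were narrow regions inside Hexb (chromosome 13, 97190542 to 97190632, 37.7-fold and 38.8-fold) and 789 kb from Ddx18 (34.8-fold and 34.9-fold). Both were also in dC replicate 2. They were followed by regions at Obscn (19.4-fold and 16.9-fold), Paxip1 and Rell2, 8.70 kb from Umodl1, and at Uevld and Arhgap23. The last lay 56.6 kb from Arap3 and 26.1 kb from Ccl6. Each of these regions had a peak in dC replicate 2 as well. These counts depend on which replicates are required: 5961 regions were in dC replicate 2 and not in wt, and 1326 in dC replicate 1 and not in wt. For YmA the values were 8790 in replicate 1 and 5017 in replicate 2.

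The comparison of the 2 mutants gave 2941 regions in both YmA libraries and in neither dC library, and 183 in both dC libraries and in neither YmA library. Without dC replicate 1, whose list was short, the counts were 3314 and 3100, and between replicates number 2 alone they were 5570 and 6330, the other direction. The other 2 splits of the 4 libraries gave 788 and 288, and 2655 and 71, so a split that mixes the mutants came close. In lists of equal length the mutants differed in 1399 regions over both directions, 829 of them particular to YmA, against 831 and 890 for the other splits. With 3 splits no exact test can reach 0.05, since the smallest p is 0.333. The regions particular to YmA were led by one inside Prodh2 (chromosome 7, 30507686 to 30508091, 28.5-fold and 20.1-fold) and by regions near Zfp704 (20.9-fold and 17.4-fold), Kcnq5 (17.3-fold and 17.4-fold), Ctnnbl1 (25.0-fold and 15.8-fold), Lrrk1 and Igkv20-101-2. Regions inside Usp15, at an end of Copb1, and near Actb and Ctbp1 completed the 10, and all 10 were also present in wt. The regions particular to dC were led by one 816 kb from Flrt2 (9.70-fold and 15.8-fold), followed by regions inside Crlf3, Erg, Apbb2, Ttll5 and Fgd3. Then came regions 110 kb from Npy, inside Unkl, 207 kb from Insc and inside Pan3. Of these 10 the regions in Erg and Apbb2 were present in wt.

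Among regions missing from exactly 2 libraries, the pair of dC libraries had the highest count. 1736 regions were present in wt and both YmA libraries and absent from both dC libraries, the highest count for any of the 10 pairs. The next were 1378 for dC replicate 1 with YmA replicate 2 and 1236 for wt with dC replicate 1. With at least 10-fold enrichment in all 3 libraries that held them, the counts were 97, 28 and 31. The 97 became 1301 without dC replicate 2, 291 without YmA replicate 2, and 4 at 15-fold. In lists of equal length the dC pair lacked 368 regions of at least 10-fold and the next pair, wt with dC replicate 1, lacked 214. At any fold these were 471 and 322. The YmA pair lacked 56 regions at any fold, or 159 in lists of equal length. The odds ratio of co-absence, which allows for how many regions each library lacks, did not single out the dC pair. It was 4.01 (CI 3.59 to 4.50) for dC and 8.67 (CI 5.52 to 13.3) for the YmA pair, the highest of the 10. In lists of equal length these were 4.74 and 8.00. The YmA interval overlapped those of other pairs, such as dC replicate 2 with YmA replicate 1 (6.66, CI 4.23 to 10.9). The strong regions were chosen for description after their values were seen. Of the 97, 47 lay inside genes, 36 between genes and 14 within 1 kb of a gene end. Beside Prodh2 and Bach2 they included regions inside Tcf12, which encodes an E protein (chromosome 9, 72012924 to 72013205, 22.5-fold in wt), and Ada, adenosine deaminase (chromosome 2, 163744821 to 163745079, 13.4-fold in wt).

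**Figure D2:**
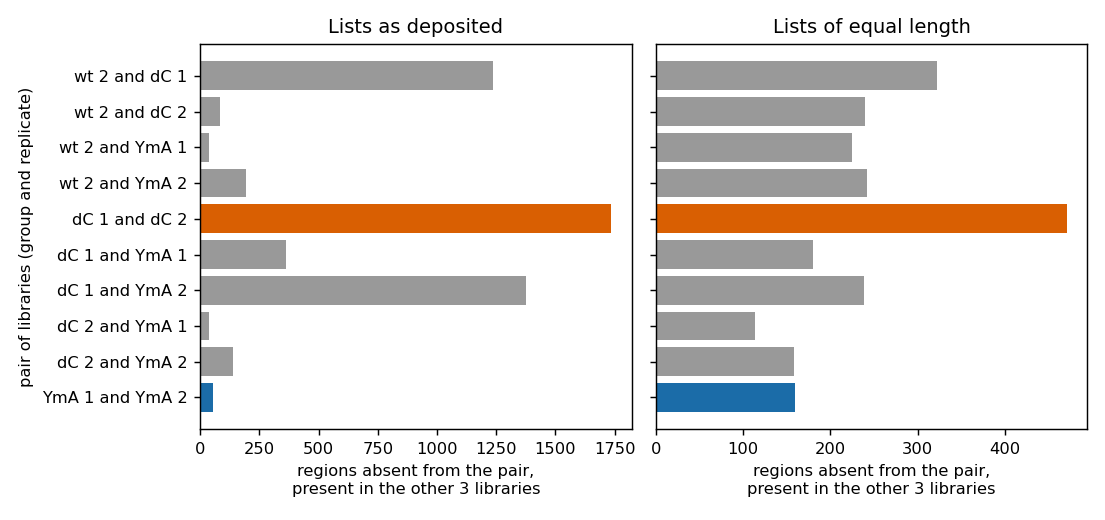
Number of regions absent from each pair of libraries and present in the 3 others (horizontal axes), for the 10 pairs (vertical axis), in the lists as deposited (left) and in lists of equal length (right); orange marks the dC pair and blue the YmA pair. The dC pair has the longest bar in both panels, 1736 and 471 regions.

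The regions missing in the mutants lay away from gene ends. 14.6% (CI 13.9 to 15.4) of the wt regions absent from both dC libraries and 11.7% (CI 10.9 to 12.6) of those absent from both YmA libraries lay within 1 kb of a gene end, against 31.7% of all wt regions and 48.0% of the regions present in all 5 libraries. Random wt regions of matched fold gave a median of 22.5% for dC and 20.1% for YmA, and none of the random sets was as low. The matching was on wt fold and not on how many libraries held a region. 48.1% of the dC-absent regions lay inside genes and 37.3% between genes. Regions in both YmA libraries and not in wt had 29.3% at gene ends, and those in both dC libraries and not in wt 18.8%. Regions in both YmA and neither dC library had 26.0%, and those in both dC and neither YmA library 4.92% (CI 2.61 to 9.08). A low share at gene ends was therefore not particular to wt regions missing in the mutants.

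T-lineage genes had 42 wt regions, of which 10 (23.8%) were absent from both dC and 3 (7.14%) from both YmA libraries. The YmA share was 19.05% in lists of equal length and 26.2% without YmA replicate 1. The dC share was 52.4% without dC replicate 2. Tcf7 and Dtx1 lacked 2 each with dC, and Lck lacked 1 and had 1 additional region with either mutant. Genes of natural killer and innate lymphoid cells lacked 7 of 17 wt regions with dC (41.2%, CI 21.6 to 64.0, percentile 90.6) and 6 with YmA (35.3%, CI 17.3 to 58.7, percentile 97.4), with Rora lacking 3 and 1. Il2rb lacked 1 with each mutant, and Klrd1 had 1 additional region in both YmA libraries. In lists of equal length 5 wt regions of this list remained, with 0 absent from dC and 1 from YmA. Myeloid genes lacked 2 and 1 of 16 wt regions, at Mpo and Siglech with dC and Fcgr3 with YmA, but 4 of 11 with either mutant in lists of equal length (percentiles 99.1 and 99.6). The same 4 regions were absent with both mutants, so the 2 percentiles are not separate results. In the full lists 0 myeloid wt regions were absent from all 4 mutant libraries. Without dC replicate 2 the dC share was 68.8%. The YmA share was 25.0% without YmA replicate 1 and 12.5% without replicate 2, against 6.25% with both. Progenitor genes lacked 5 and 2 of 20, including Meis1 and Lmo2, while Flt3 had 2 additional regions in both YmA libraries. In lists of equal length the progenitor shares were 15.4% with dC and 23.1% with YmA, against 25.0% and 10.0%. The dC share was 45.0% without dC replicate 2. Erythroid and megakaryocyte genes lacked 3 and 2 of 14, at Itga2b and Hbb-bt with both mutants and Gp9 with dC. None of their 8 wt regions was absent with either mutant in lists of equal length. Their YmA share was 28.6% without YmA replicate 1, against 14.3% with both. Hepatocyte and stromal genes lacked 2 and 0 of 5, both at Pdgfrb, and Trf and Hnf4a each had 1 additional region with YmA. Housekeeping genes lacked 4 and 3 of 32, with Actb lacking 2 and 1, and Ubc and Rpl13a 0. The housekeeping share with dC was 31.3% without dC replicate 2, against 12.5% with both, and 0 of 22 wt regions were absent at equal list length. With loci taken as the nearest gene, an alternative chosen after the data were seen, the YmA share was 3.03% against 9.38%.

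At Ebf1 itself (chromosome 11) 18 regions were found, 14 in wt, 6 and 9 in dC and 11 and 12 in YmA. 6 were in all 5 libraries, led by chromosome 11, 44617138 to 44617437, with folds of 17.3 in wt, 16.7 and 16.3 in dC and 25.1 and 20.8 in YmA. The cells lack endogenous Ebf1 and carry a transduced copy, whose reads would map to Ebf1 exons. Exons were not annotated here, so these peaks do not check the labels.

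The immunoglobulin kappa light chain locus, Igk, was examined after its values were seen. Over chromosome 6, 67545636 to 70736754, wt had 71 regions, dC 4 and 13, and YmA 42 and 22. This is 2.44 per 1000 regions of the library in wt (CI 1.93 to 3.07), 0.290 and 0.501 in dC, and 1.32 and 0.874 in YmA. Of the 71 wt regions, 57 (80.3%) were absent from both dC libraries and 31 (43.7%) from both YmA libraries. The 31 were absent from all 4 mutant libraries. Without YmA replicate 1 the count for YmA was 51. Of 35 regions with at least 10-fold enrichment in wt, 24 were absent with dC and 6 with YmA. The immunoglobulin heavy chain locus, Igh, on chromosome 12 had 99 regions in wt, 52 and 97 in dC and 98 and 94 in YmA, and none of its 45 wt regions of at least 10-fold was absent from both libraries of either mutant. The 2 YmA counts at Igk both lay above the 2 dC counts, but 2 against 2 libraries cannot give an exact p below 0.333. In lists of equal length wt had 37 Igk regions, dC 4 and 5, and YmA 11 and 10. Of these 37, 31 were absent from both dC libraries and 26 from both YmA libraries, so the mutants differed less.

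**Figure D3:**
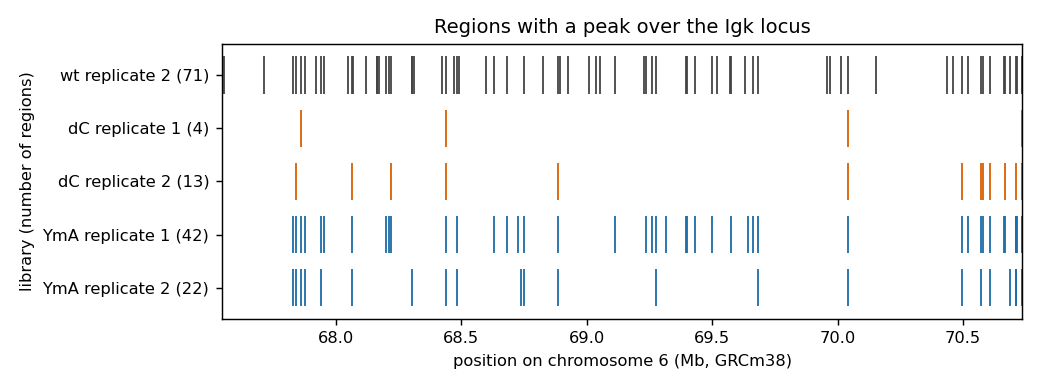
Regions with a peak over the Igk locus in each library (rows, with the number of regions in parentheses) along chromosome 6 in Mb (horizontal axis, GRCm38); each vertical line is 1 region. wt has 71 regions, dC replicates 1 and 2 have 4 and 13, and YmA replicates 1 and 2 have 42 and 22.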

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

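Peaks outside the chromosomes compared were found in every library. The mitochondrial genome held 9 peaks in wt, 11 and 10 in dC replicates 1 and 2, and 8 and 9 in YmA replicates 1 and 2. Unplaced contigs held 15 peaks in wt, 10 and 16 in dC and 15 and 15 in YmA. Chromosome Y held 5 peaks in YmA replicate 1 and 6 in YmA replicate 2, against 3 in wt and 1 and 2 in dC. All of these peaks were left out of the main comparisons. Counts above 3 in a library were flagged, which left out the Y counts of wt and dC. Those are also peaks that passed the authors' threshold, so the limit does not make them equal to 0.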

How the results depend on the processing

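The 15-fold limit, the gene-end window of 2.5 kb, the nearest-gene loci and all alternatives for the strong regions and Igk were chosen after seeing the data. A stricter q, an overlap of 50% and summits within 250 bp left each count of absent or additional regions within 1.5 times its value, as did all contigs, which were not run for the strong regions, Igk and the overlap of lists. Of 111 comparisons with an alternative over the main results, 37 moved, a count by over 1.5 times, a share beyond its 95% interval or a Jaccard difference beyond 1 SD. Lists of equal length gave 2562 wt regions absent from dC, 2163 from YmA and 1492 from all 4 libraries, which is also the overlap of the 2 lists. They gave 1552 regions in both dC and 1594 in both YmA libraries without wt, 829 particular to YmA and 570 to dC, 368 strong regions and 31 Igk regions absent from dC. Shorter lists hold fewer weak peaks, but the cause of each move was not tested. At 15-fold 4 strong regions were left. With replicate number 2 only, 8968 wt regions were absent from YmA, 5961 dC and 5017 YmA regions were not in wt, 5570 were particular to YmA and 6330 to dC, since 1 library in place of 2 then decides. The gene-end share of dC-absent regions was 15.7% with the stricter q, 19.01% in equal lists and 22.0% with 2.5 kb. The shares of all wt regions and of random sets were not taken at these settings. These values therefore do not test the difference from other wt regions.

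Leaving out each mutant replicate in turn gave 9152 to 16652 wt regions absent from dC (highest without dC replicate 2) and 6206 to 8968 from YmA (highest without YmA replicate 1). Regions not in wt ranged from 1326 to 5961 for dC and from 5017 to 8790 for YmA. Those particular to YmA ranged from 3314 to 9821, and to dC from 292 to 3100. Strong regions ranged from 119 to 1301, with 1301 without dC replicate 2 and 291 without YmA replicate 2. Igk regions absent from YmA ranged from 33 to 51 (highest without YmA replicate 1). B programme shares ranged from 21.3% to 51.7% for dC and from 13.5% to 21.3% for YmA. Of 100 comparisons for the other gene lists 19 moved outside the interval. No paired analysis was possible because wt has 1 library, and for dC against YmA the counts hold no fitted effect that a pairing could alter. A region in both YmA and neither dC library differs the same way within both numbers, so its count is the same with the numbers as pairs. Presence deviations of same-numbered mutant libraries correlated at 0.0183. The EBF motif search and nearest TSS were not run. Unknown depth limits all counts of absent regions.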

Other observations

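Further regions of the set held at 10-fold or more by wt and both YmA libraries and absent from both dC libraries lay at an end of Il4ra, a chain of the interleukin 4 receptor (chromosome 7, 125552109 to 125552287, 12.9-fold in wt), and of Hdac2, a histone deacetylase (13.1-fold). Regions inside Camk2d (17.0-fold), Msi2 (18.4-fold) and Inpp4b (11.4-fold) belonged to it too. So did regions between genes whose nearest gene encodes a transcription factor: Mef2a (38.4 kb away, 19.9-fold), Epas1 (37.5 kb, 19.8-fold), Zbtb18 (59.3 kb, 14.7-fold), Klf13 (83.9 kb, 12.8-fold) and Bcl6 (163 kb, 10.4-fold). These were picked from the 97 after their values were seen.

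Of the tests below, the one that leaves out sister libraries was fixed before its result was seen, and the others were chosen afterwards.

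Regions with at least 10-fold enrichment in wt and both YmA libraries and absent from both dC libraries numbered 97, and the highest other pair of libraries lacked 31, but the 97 became 1301 without dC replicate 2, 291 without YmA replicate 2 and 4 at 15-fold. Shorter or noisier dC lists stay open. At equal list length the dC pair lacked 368 such regions and the highest other pair 214, and among wt regions of at least 10-fold 613 were in YmA replicate 2 and not in dC replicate 2, and 353 the reverse, although dC replicate 2 has the longer list. Over all wt regions these were 2651 and 2467, and the odds ratio of co-absence of the dC pair in lists of equal length, 4.74, was below the 8.00 of the YmA pair. Of the 10 pairs 1, the dC pair itself, reached 97, and 10 pairs are too few for a share under 0.05, so an effect of dC remains a hypothesis.

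At Igk, shorter mutant lists do not account for the pattern, since in lists of equal length wt had 37 regions and the highest mutant library 11. For dC, a gain of signal over a wider part of chromosome 6 in wt is argued against as the whole cause by the neighbouring windows of the same length, where at most 48.1% of wt regions were absent from dC, with an upper limit of 66.0%, against 80.3% (CI 69.6 to 87.9) at Igk, the highest of 495 windows, the next of which reached 72.0%, although the 48.1% itself ranked 15 against a median of 29.2% and came with 15 wt regions against 8 and 11 with dC in equal lists. For YmA it stays open: the Igk share of 43.7% (CI 32.7 to 55.2) ranked 4 among the windows, below a highest of 55.0%, and the neighbouring windows reached 25.9% with an upper limit of 44.7%, while without YmA replicate 1 the 31 absent Igk regions became 51. Opening of Igk accompanies the step from pro-B to pre-B cells, so wt cells may be further along B-cell development than dC cells, with YmA between. In lists of equal length the YmA libraries, with 11 and 10 Igk regions, lay nearer to dC, with 4 and 5, than to wt. The later B-cell list lay at percentile 67.0 of random lists with dC and 20.4 with YmA. It cannot decide this, since it holds 25 wt regions, was not chosen for the step to pre-B cells, and includes Igkc in Igk itself. The CD19 sort does not separate these stages. A later stage of the wt cells, a change limited to Igk in the single wt library and an effect of EBF1 form therefore stay open.

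The 4357 regions found in wt alone may in part be weak peaks near the calling threshold, since 91.5% of them had a fold below the wt median. At equal list length wt had 1492 private regions, below the 1875 of dC replicate 1 but above the 998 of dC replicate 2 and the 636 and 880 of YmA replicates 1 and 2, which leaves this open. Among private regions of at least 10-fold, wt had 245 and the other libraries at most 101, but wt alone has no second library of its group. With YmA replicate 2 left out, wt had 306 and YmA replicate 1 had 228, a ratio of 1.34, while the ratio was 6.15 against dC replicate 2 and 4.98 against YmA replicate 2 with their sister libraries left out, and dC replicate 1 had 0 such regions. The missing second wt library therefore cannot be told apart from a difference of wt for these regions, because the mutant libraries disagree.

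The 2 narrow regions at Hexb and 789 kb from Ddx18 had folds of 31.8 and 27.6 in dC replicate 2, and no peak in wt or dC replicate 1.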
